A study of Mus musculus with 4 samples.

How the data were processed

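Single-cell 3′ libraries of CD45+ cells were analysed from 4 samples, 1 female and 1 male library of each Csf2 genotype. The deposited matrices hold whole-number UMI counts per gene and cell barcode, not normalized, made with Cell Ranger 7.0.0 against GRCm39 per the submitters' processing notes. Per the series' design text each library was pooled from 2 mice, and the deposited matrices list barcodes that had been called as cells. The annotation at hand is of another mouse build, so no coordinates are given and genes carry the names in the deposited files. Of 26033 features, 312 share a symbol with another and were kept apart by identifier. Total UMIs ran from 111981802 to 122366588 per library, with 2 libraries per genotype.

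Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, 37644 of 39395, with 17729 genes seen in at least 10 cells. Doublets were scored per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.008 per 1000 barcodes. Its automatic threshold was used in the Csf2+/- female and Csf2-/- male libraries. In the other libraries it marked 0.0343% and 0% of barcodes, so the expected share with the highest scores was removed, as set beforehand. This left 34382 cells. Counts were scaled to one total per cell, log-transformed and reduced to 40 principal components of 3000 variable genes, ranked within library and leaving out immunoglobulin, T cell receptor variable, mitochondrial, ribosomal and sex-linked genes. Cells were clustered with 15 nearest neighbours by Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.5 with seed 1 and no batch integration. The 54 clusters were named from fixed marker sets into 16 classes called X-like. The 11 clusters led by markers of another lineage, or with too few markers, stayed unnamed. The names are rebuilt here and can differ from the study's own.

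UMI counts were summed per library and class. Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust dispersion, TMM normalization and the default low-count filter. Genotype was the only term, which left 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within a class at a threshold of 0.05. The 12 classes with at least 50 cells in every library were tested. Class shares were tested with edgeR on cell numbers for the 14 classes with at least 100 cells, with the library's cell total as its size. Sex was tested in macrophage-like cells in a model with genotype, which left 1 residual degree of freedom. Gene lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Adjusted p-values of lists run over the lists of a class. Shares of cells carry exact binomial 95% intervals (scipy 1.17.1). Levels are given as CPM, computed here from the summed counts. The SE of an edgeR log2 change was derived from its test, as the size of the change divided by the square root of the F statistic.

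The lists were alveolar-type, STAT5-induced, GM-CSF and related receptor, MHC class II, perivascular-type, CX3CR1-type and lipid-associated macrophage genes, cholesterol synthesis, glycolysis, proliferation, interferon response, inflammatory cytokines, efferocytosis and complement, lysosome, matrix and growth factors, monocyte-derived and dendritic genes, dissociation stress, ILC2 effector genes, genes near Csf2, salivary epithelium, red cell genes, the mitochondrial genome and sex-linked genes. Some genes are on more than 1 list. The samples, tests, lists, markers, filters and other settings to be tried were fixed before the data were examined.

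Genes to be named were fixed by a rule. In macrophage-like cells these were, among genes past 0.05 with a mean of at least 10 CPM and both libraries of a genotype above both of the other, the 10 with the largest rise and the 10 with the largest fall, up to 4 members of each list by p, and a set of GM-CSF receptor and macrophage genes. In each other class with calls the rule took up to 4 genes in each direction, but more were taken in cDC2-like cells (19 genes) and cluster 14 (32). The rule named 210 genes, 101 of them in macrophage-like cells, of which the text gives a part. Of the 210, the 32 in cluster 14, 8 in macrophage cluster 4 and 4 in macrophage cluster 6 belong to units singled out after the data were seen. Another 126 were chosen after their values were seen. They are called members of the lists in cluster 14, macrophage cluster 4 and the dendritic-like and monocyte-like classes, members of lists that passed in another class, and genes of classes with 5 calls or fewer.

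The genotype tests of 4 units, the test of shares, the list test in macrophage-like cells and the sex test were tested on simulated data drawn from the means and sizes of the real libraries. Genes were drawn independently of each other, in the gene tests with the spread of the fitted trend. The genotype simulations held no sex difference, so recovery in the real data can be lower than given here. In macrophage-like sums (12503 genes) edgeR recovered 26.9%, 80.7% and 98.4% of genes changed 1.5, 2 and 4 times, in cDC2-like sums (10676 genes) 37.0%, 70.8% and 95%, and in cluster 14 (9598 genes) 27.4%, 67.1% and 87.5%. In monocyte-like sums (9499 genes) the shares were 36.6%, 71.0% and 96.7%. The sex test in macrophage-like sums (12510 genes) recovered 61.0%, 81.7% and 97.5%, with 7 of 12312 unchanged genes called. In the simulated shares the spread between libraries was set by hand and not taken from the data, so these rates can be better than in the real libraries. Over 100 simulations the share test called the migratory dendritic-like class, cut to 0.25 of its share, in 92%. The eosinophil-like class, raised 4 times, was called in 96%, and 0.923% of tests of unchanged classes gave a call. Camera called 100% of lists shifted by 0.3 log2 and 0.1% of unshifted lists, in data without correlation between genes.

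DESeq2 gives no adjusted p to genes under its own filter on mean counts, and these were left out of the numbers of lost calls. The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, other low-count filters, sex as a block, doublets kept, at least 1000 UMIs and at most 5% mitochondrial UMIs, equal median depth or equal numbers of macrophage-like cells, 3000 UMIs per cell for macrophage subsets, dividing clusters left out, TMM factors for shares, mononuclear phagocytes as denominator, Leiden resolution 0.8 and each library left out in turn. Added after seeing the data were tests of cluster 14 and of macrophage clusters 4 and 6, clustering without the leading genes of cluster 14, leaving out lymphocyte-led macrophage subsets or Y-positive cells of the Csf2-/- female library, lists in other classes , the 1000 UMI and the 5% mitochondrial limits each alone for shares, and the thinning of Csf2 shares to 3000 UMIs per cell. Numbers were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9. Classes with fewer than 50 cells in a library were left out of gene tests, since their sums hold few counts.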

Results

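CD45+ cells, which are leukocytes, were taken from the salivary glands of mice at 20 days of age, enriched with magnetic beads, sorted by flow cytometry and profiled by droplet single-cell RNA sequencing. Csf2 encodes GM-CSF, a growth factor for myeloid cells. Mice with 1 functional Csf2 allele (Csf2+/-) were compared with mice lacking both (Csf2-/-), with 1 female and 1 male library per genotype (n = 2 libraries per genotype, each pooled from 2 mice). The series concerns gland macrophages that depend on GM-CSF from group 2 innate lymphoid cells (ILC2s), so the comparison asks which cells and genes differ when GM-CSF is missing. The Csf2+/- female and male libraries held 122366588 and 113728825 UMIs in 10065 and 9322 barcodes, and the Csf2-/- female and male libraries 111981802 and 116465859 UMIs in 10090 and 9918 barcodes. The median UMIs per barcode were 10586, 10085.5, 8953 and 9003 in that order, so the Csf2-/- cells were read less deeply. After filtering and removal of predicted doublets, 8925, 8055, 8953 and 8449 cells remained. The p-values of the gene and share tests rest on the spread between these pools. That spread is estimated in part from the other genes or classes of a test, so it is not that of a single gene or class alone. With genotype as the only term that spread includes the difference between the sexes, since each genotype has 1 female and 1 male library. Camera with a preset correlation compares a list with other genes, and a sign test counts genes, so neither measures the spread between pools. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.33.

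Csf2 transcripts were concentrated in ILC2-like cells and were much lower there in both Csf2-/- libraries. The level was 134.4 ± 11.2 CPM in Csf2+/- and 6.19 ± 0.659 CPM in Csf2-/- ILC2-like cells (SD, n = 2 per genotype; log2 fold change -4.45, SE 0.11, edgeR adjusted p = 1.41e-07). A Csf2 UMI was found in 24.4% (exact 95% interval 22.1 to 26.7) and 26.7% (24.3 to 29.2) of Csf2+/- ILC2-like cells. In the Csf2-/- female and male libraries the shares were 4.73% (3.66 to 6.00) and 4.32% (3.49 to 5.28). In all other cells the shares were 0.979% and 0.859% in Csf2+/- and 0.145% and 0.126% in Csf2-/- libraries. The median depth was 9704, 8965, 8091 and 7923 UMIs in ILC2-like cells and 10859, 10496, 8963.5 and 9120 in the others. With every cell thinned to 3000 UMIs, the ILC2-like shares were 13.4%, 15.7%, 1.67% and 1.11%, leaving out 13, 17, 36 and 37 shallower cells. The thinned shares of other cells were 0.414%, 0.370%, 0.0853% and 0.0694%, with 551, 535, 570 and 584 cells left out. The labels do not say which part of Csf2 is deleted, so a 3′ tag outside that part would check nothing. The intervals cover counting error only.

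**Figure D1:**
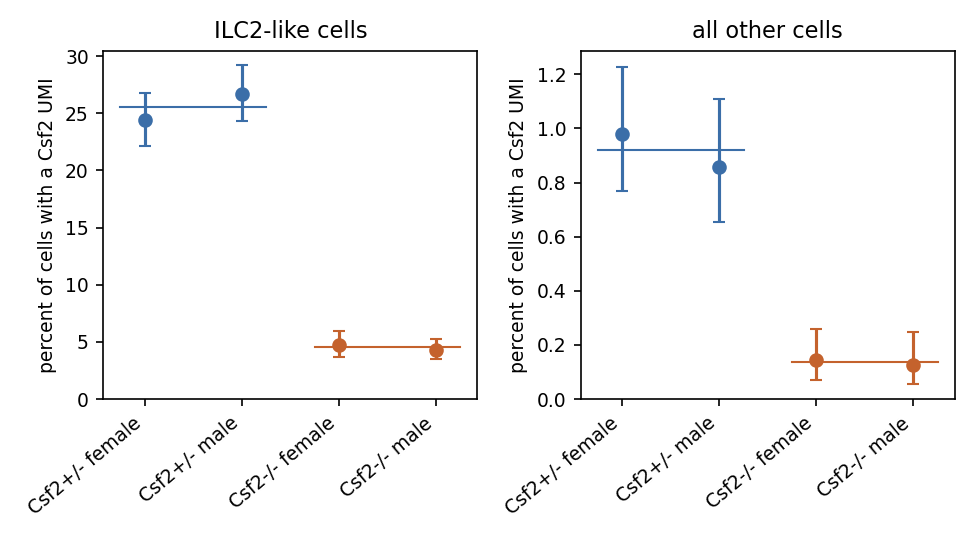
Percent of cells with at least 1 Csf2 UMI per library (points, bars give the exact 95% interval, horizontal lines the genotype mean) in ILC2-like cells and in all other cells, on separate scales that start at 0. The Csf2-/- ILC2-like shares of 4.73% and 4.32% lie below the Csf2+/- shares of 24.4% and 26.7%.

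In macrophage-like cells, no gene passed the test, and the lowest p-values included genes induced through the GM-CSF receptor. Ccl22, a chemokine of that kind, stood at 4.09 ± 0.219 CPM in Csf2+/- and 0.968 ± 0.0229 CPM in Csf2-/- cells (SD, n = 2 per genotype; log2 -2.08, SE 0.27, edgeR adjusted p = 0.176). Ccl22 also leads the migratory dendritic-like cells, at 2602 CPM in Csf2+/- libraries, where it fell. Jak2, the kinase bound to the receptor, had 55.1 ± 0.414 and 40.99 ± 1.80 CPM (log2 -0.44, SE 0.09, adjusted p = 0.319), and Lpl, which encodes lipoprotein lipase, 457.4 ± 30.2 and 321.1 ± 12.4 CPM (log2 -0.52, SE 0.09, adjusted p = 0.319). The receptor chains Csf2ra, Csf2rb and Csf2rb2 had log2 changes of -0.07, -0.31 and -0.28, and Csf1r, the receptor of the other macrophage growth factor, -0.08. Markers of resident macrophages had log2 changes of 0.90 (Lyve1, SE 0.43), 0.33 (Cd163), 0.27 (Mrc1), 0.13 (Folr2), -0.07 (Cx3cr1), -0.16 (Adgre1), -0.17 (Itgax) and -0.24 (Pparg). Fn1 (log2 -1.45) and Lyz1 (log2 -0.53, and 0.18 with doublets kept) also lead cluster 14, described further on, as does Lpl. Icos and Bcl11b, lymphocyte genes, had log2 changes of 1.25 and 1.504 (edgeR adjusted p = 0.176 for both). Subsets of macrophage-like cells led by lymphocyte genes held 5.12% and 4.37% of these cells in Csf2+/- and 7.29% and 8.28% in Csf2-/- libraries, and without those subsets the change of Icos was -1.28.

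Over 12669 genes in macrophage-like cells, edgeR called 0 higher and 0 lower in Csf2-/- libraries, with 1225 at an unadjusted p under 0.05. DESeq2 called 13 higher and 17 lower, and limma-voom 0 with 1198 at an unadjusted p under 0.05. With sex as a block the counts were 150 higher and 287 lower. Without the Csf2-/- female library they were 198 and 201, and without the Csf2-/- male library 32 and 17.

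Several gene groups lay to one side in Csf2-/- macrophage-like cells, with 0 of their members past edgeR over all genes. At an unadjusted p under 0.05 edgeR had 7 STAT5-induced, 5 lysosomal, 4 cholesterol, 4 mitochondrial and between 1 and 3 members of each other list reported as passing here. DESeq2 called 2 STAT5-induced genes lower, 2 ILC2 effector genes higher and 1 lipid-associated, 1 matrix and 1 mitochondrial gene lower. Of 25 genes induced through STAT5, 17 had lower values (median log2 -0.19), and 5, adjusted over the list alone, passed as lower. Of 14 MHC class II genes, which serve antigen presentation, 13 had lower values (median -0.32), among them H2-Aa (log2 -0.44, SE 0.24) and Ciita (-0.36, SE 0.16). Of 29 lysosomal genes 26 had lower values (median -0.12), including Npc1 (-0.32) and Atp6v1a (-0.28). In the other direction, 27 of 30 proliferation genes had higher values (median 0.35), such as Pclaf (0.50, SE 0.19) and Tyms (0.50, SE 0.17), and so had 20 of 23 markers of perivascular-type macrophages (median 0.23). By camera with a preset correlation these lists passed with adjusted p = 0.00701 (STAT5), 0.00701 (MHC class II), 0.00139 (lysosome), 0.000394 (proliferation) and 0.00866 (perivascular). The list of GM-CSF and related receptor genes (9 measured, 8 lower, adjusted p = 0.0106), lipid-associated genes (23 measured, 18 lower, 0.0228) and matrix and growth factor genes (26 measured, 19 lower, 0.0359) also passed as lower. Each of these had 1 lower member adjusted over the list alone. Cholesterol synthesis (21 measured, 14 higher, adjusted p = 0.0179), interferon response (31 measured, 25 higher, 0.0190) and ILC2 effector genes (22 measured, 17 higher, 0.00515) passed as higher, the last with 2 higher members adjusted over the list alone. Transcripts of the mitochondrial genome, a sign of RNA quality, passed as lower alongside them (13 measured, 9 lower, median -0.21, adjusted p = 0.00701), with 1 lower member adjusted over the list alone. None of these 12 calls held with an estimated correlation, where adjusted p = 0.686 for each with an estimated correlation, or by fry, where adjusted p was 0.275 or more.

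The other 11 lists did not pass in macrophage-like cells. They were alveolar-type genes (18 measured, adjusted p = 0.0935, with 1 lower adjusted over the list alone), dendritic genes (16 measured, 0.0650), CX3CR1-type genes (13 measured, 0.437) and glycolysis (16 measured, 0.685). Adjusted p = 0.617 was found for inflammatory cytokines (20 measured), efferocytosis and complement (17 measured, 1 lower adjusted over the list alone), monocyte-derived genes (17 measured, 1 higher and 1 lower adjusted over the list alone) and dissociation stress (22 measured). The same value held for the genes near Csf2 (28 measured) and the sex-linked genes (4 measured). Salivary epithelial genes (23 measured) had adjusted p = 0.437. The median and the test differed in sign for inflammatory cytokines (median 0.04), efferocytosis (0.04) and sex-linked genes (-0.17). Of the red cell genes Hba-a1 and Hbb-bs were measured, too few for a list test, and their mean levels in Csf2-/- cells of 61.9 and 162.5 CPM came almost wholly from the female library. The number of lists past the threshold was 3 without the Csf2+/- female library and 7 without the Csf2-/- male library.

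**Figure D2:**
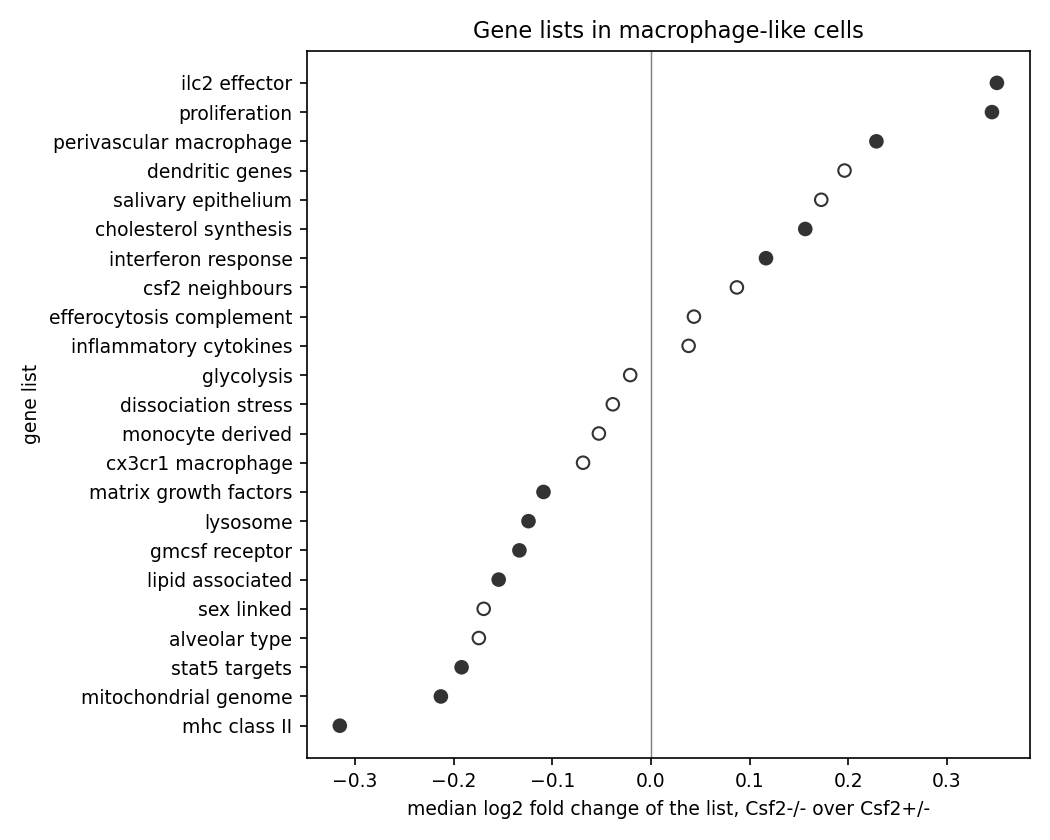
Median log2 fold change, Csf2-/- over Csf2+/-, of the measured members of 23 gene lists in macrophage-like cells; filled points passed an adjusted p of 0.05 by camera with a preset correlation and open points did not. Medians run from -0.32 for MHC class II genes to 0.35 for ILC2 effector and proliferation genes.

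Within the macrophage-like cells, the larger of the clusters, cluster 4, showed changes past the test. Retnla fell from 20.2 ± 2.91 to 1.04 ± 0.293 CPM (SD, n = 2 per genotype; log2 -4.22, SE 0.29, edgeR adjusted p = 1.46e-05). Jak2 (log2 -0.71, SE 0.10), Bcl2l1, which protects against cell death (-0.49, SE 0.08), and the chemokine genes Ccl22 (-1.99, SE 0.36) and Ccl17 (from 2.16 to 0.146 CPM) fell too, while Mrc1, the mannose receptor gene, rose (0.83, SE 0.12). Retnla also leads cluster 14, at 10231 CPM there in Csf2+/- libraries, and NK and ILC1-like cells held it at 10.9 CPM in Csf2+/- and 1.24 CPM in Csf2-/- libraries. Ccl22 and Ccl17 are among the leading genes of migratory dendritic-like cells, with Ccl22 at 2602 CPM there against 5.71 CPM in cluster 4. RNA from these other cells was not separated from that of cluster 4. Of 25 STAT5-induced genes, 3 fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.909 with an estimated correlation). Cluster 4 had 5 genes higher and 32 lower of 10901, and cluster 6, the next in size, 1 higher and 3 lower of 10509. The higher gene in cluster 6 was Igkc, an antibody light chain gene (log2 1.99), and the lower ones were Kansl1l, Reps2 and Sik3 (-0.75, -0.81 and -0.75). Of 14 ILC2 effector genes in cluster 4, Ccl1 rose (2.41, SE 0.46), with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000848, and adjusted p = 0.909 with an estimated correlation). In cluster 4 the mitochondrial transcripts had a median log2 change of -0.24, with 4 lower adjusted over the list alone (camera adjusted p = 0.00805, and adjusted p = 0.909 with an estimated correlation). Without single libraries the calls in cluster 4 numbered 3 (Csf2+/- female), 4 (Csf2+/- male), 272 (Csf2-/- female) and 156 (Csf2-/- male), and in cluster 6 they numbered 0, 0, 508 and 103. They were 47 higher and 146 lower in cluster 4 and 121 and 125 in cluster 6 with sex as a block, and by DESeq2 Bcl2l1 did not pass (adjusted p = 0.0881). For Ccl22, Ccl17 and Ccl1 in cluster 4 and Igkc in cluster 6 DESeq2 gave no adjusted p, and it called 0 of the STAT5-induced and 0 of the ILC2 effector genes in cluster 4. Apart from Retnla, the genes named in cluster 4 did not pass without the Csf2+/- female or without the Csf2+/- male library (adjusted p from 0.147 to 0.509), and Ccl17 did not without the Csf2-/- female (0.107) or male library (0.0642) either, nor Ccl1 without the Csf2-/- male library (0.0831). Both clusters were tested on their own after the data were seen. Cluster 4 held 41.98% and 37.3% of Csf2+/- and 42.3% and 29.6% of Csf2-/- macrophage-like cells, and cluster 6 held 26.1%, 30.5%, 26.2% and 35.3%, so cluster 6 was the larger in the Csf2-/- male library.

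Eosinophil-like cells, granulocytes that answer to type 2 cytokines, made up a smaller share of the Csf2-/- libraries, and the other 13 named classes tested did not pass. Eosinophil-like cells were 2.24 ± 0.262% of Csf2+/- and 0.854 ± 0.149% of Csf2-/- cells (SD, n = 2 per genotype; log2 -1.39, SE 0.38, edgeR adjusted p = 0.0149), lower in both sexes. Macrophage-like cells were 14.7 ± 1.67% and 17.8 ± 0.275% (log2 0.27, SE 0.35, adjusted p = 0.717), and ILC2-like cells 15.7 ± 0.558% and 20.0 ± 6.93% (log2 0.35, SE 0.35, adjusted p = 0.665). NK and ILC1-like cells, the most numerous class, were 32.6 ± 1.92% and 24.9 ± 4.89% (log2 -0.39, adjusted p = 0.644). Gamma-delta T-like cells were 3.61% and 1.30% of Csf2+/- libraries and 5.31% and 5.01% of Csf2-/- libraries (log2 1.07, SE 0.42, adjusted p = 0.137), with changes of 1.98 without the Csf2+/- female and 0.51 without the Csf2+/- male library. Migratory dendritic-like cells were 1.59 ± 0.0928% and 0.946 ± 0.153% (log2 -0.75, SE 0.38, adjusted p = 0.264). As a share of the named mononuclear phagocyte classes the migratory class fell (log2 -0.88, edgeR adjusted p = 0.00251). That denominator left out cluster 14, a myeloid cluster that was itself rarer in Csf2-/- libraries. The migratory class did not pass as a share of all cells, and whether it passes with cluster 14 in the denominator is not shown. The other 8 of 14 classes tested had log2 changes between -0.61 (B-like) and 0.66 (epithelial-like), with adjusted p = 0.297 or more. Unnamed clusters, cluster 14 included, held 9.25 ± 0.929% and 9.65 ± 1.26%. Cluster 14 alone held 3.70% and 0.734%, so the other unnamed clusters together were a larger share of Csf2-/- than of Csf2+/- cells. That difference was not tested.

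The median UMIs of eosinophil-like cells were 762, 664, 815 and 769 per library. With at least 1000 UMIs per cell and the other filters kept, 36, 27, 18 and 21 of them were left and the change was -0.73 (SE 0.46, adjusted p = 0.334). With at most 5% mitochondrial UMIs and the other filters kept it was -1.42 (SE 0.39, adjusted p = 0.0157), and with both limits -0.83 (adjusted p = 0.322). The call was also lost with sex as a block (adjusted p = 0.0995), without the Csf2+/- female library (0.148) and without the Csf2+/- male library (0.665). Shares depend on the CD45 sort, the filters and the doublets removed (6.71%, 7.94%, 8.19% and 11.8% of barcodes).

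**Figure D3:**
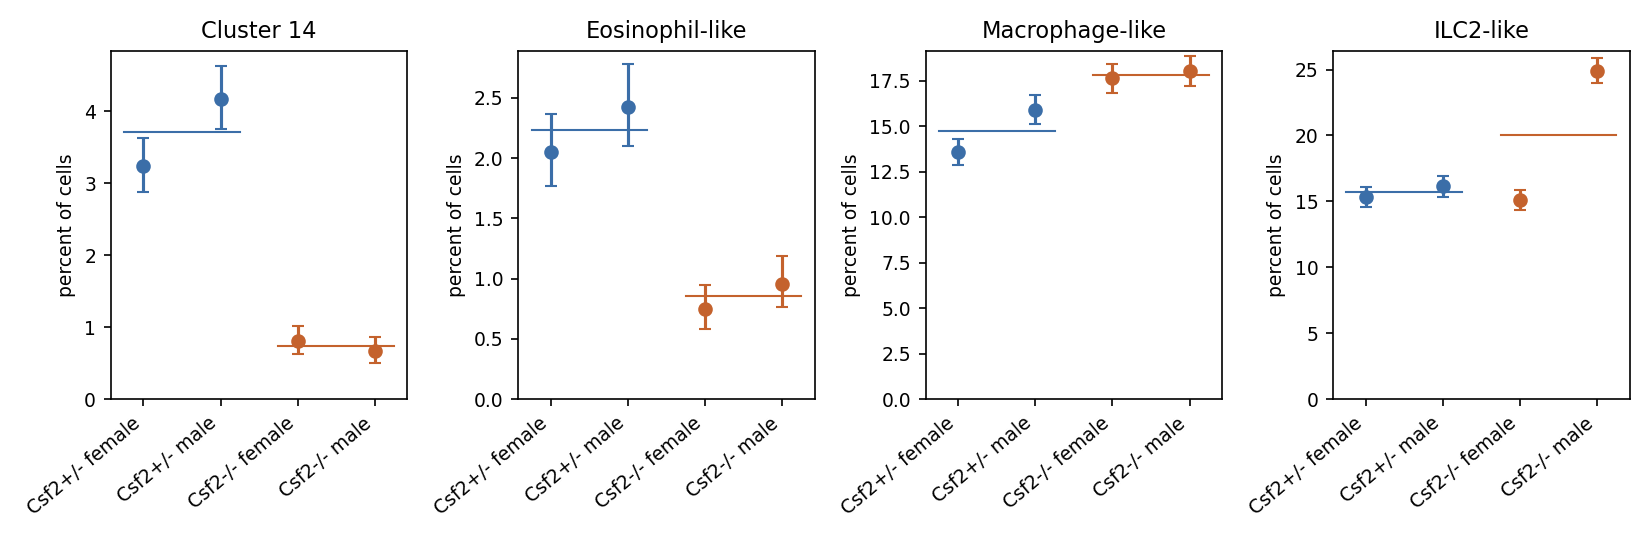
Percent of cells per library (points, bars give the exact 95% interval, horizontal lines the genotype mean) for cluster 14 and for eosinophil-like, macrophage-like and ILC2-like cells, on separate scales that start at 0. Cluster 14 held 3.24% and 4.17% of Csf2+/- cells against 0.804% and 0.663% of Csf2-/- cells.

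A myeloid cluster, cluster 14, was several times rarer in both Csf2-/- libraries. Because genes that lead it also differ by genotype, the share was taken from a clustering without its 100 leading genes and without all genes called between genotypes in any class. There the group made up mostly of cluster 14 cells held 2.97% and 3.86% of Csf2+/- cells and 0.949% and 0.994% of Csf2-/- cells (log2 -1.81, SE 0.37, edgeR adjusted p = 0.000462). That clustering placed 79.3% of the cells of cluster 14 in 1 group. The group was picked by its overlap with cluster 14, so altered Csf2-/- cells grouped elsewhere would not be counted. Whether cells were reassigned is therefore not decided by this share. In the first clustering the share was 3.70 ± 0.66% and 0.734 ± 0.10% (SD, n = 2 per genotype; log2 -2.33, SE 0.38, adjusted p = 1.56e-05). The cluster is led by Retnla, Fn1, Lyz1, Lpl and Lyz2, and it expressed 9 of 12 macrophage markers and 7 of 11 cDC2 markers at 50 CPM or more, so it was left unnamed. Doublets were 11.3% of its barcodes, against 12.6% of macrophage-like, 17.8% of cDC2-like and 8.67% of all barcodes. At Leiden resolution 0.8 it was not a cluster of its own: 752 of its 753 cells joined a cluster of 2060 cells led by Retnla, Fn1 and Cd209a that was named cDC2-like. The change in the cDC2-like share was -0.66 there (SE 0.35, adjusted p = 0.190), against -0.08 at the resolution used. Cluster 14 was singled out after the data were seen, and with sex as a block the first clustering gave adjusted p = 0.0526.

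The cells of cluster 14 that remained in Csf2-/- libraries (72 and 56, against 289 and 336) differed in named genes. Flrt3, an adhesion molecule gene, fell from 92.9 ± 11.3 to 2.79 ± 0.417 CPM (SD, n = 2 per genotype; log2 -4.96, SE 0.31, edgeR adjusted p = 8.72e-06). Cebpe, a transcription factor gene of granulocyte development, fell by 3.08 on the log2 scale (SE 0.36), Igf1, a growth factor gene, by 2.49 (SE 0.28), and Vdr, the vitamin D receptor gene, by 2.45 (SE 0.32). Mmp12, a macrophage elastase gene, fell by 2.09 (SE 0.17). Gdf15 (log2 3.48, SE 0.60), Il4i1 (2.46, SE 0.36), Gpr183 (1.84, SE 0.19) and Tnfsf9 (1.62, SE 0.17) rose. Il4i1 is also a leading gene of migratory dendritic-like cells. Of 25 STAT5-induced genes, 5 fell, including Socs2 (-2.24) and Cish (-1.54), 2 rose, Gpr141 (1.27) and Socs3 (0.67), and 18 did not pass. Adjusted over the list alone, 7 were lower and 4 higher (camera adjusted p = 0.0702, and adjusted p = 0.679 with an estimated correlation). Of 23 perivascular-type markers 2 fell, Igf1 and Mrc1 (-0.60), 1 rose, Clec10a (1.02), and 20 did not pass (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00245, and adjusted p = 0.679 with an estimated correlation). Of 14 MHC class II genes, H2-DMb2 (-2.21) and Cd80 (-1.27) fell, H2-Eb1 (0.58), H2-Ab1 (0.54), H2-Aa (0.51) and Cd74 (0.40) rose, and 8 did not pass. The class II list as a whole did not pass (4 lower and 6 higher adjusted over the list alone, camera adjusted p = 0.153). H2-Eb1, H2-Ab1, H2-Aa, Cd74 and Clec10a also lead cDC2-like cells. A shift in which cells make up cluster 14 was not told apart from changes within its cells. The mitochondrial list was lower in the same cells, with mt-Nd3 (-1.03) and mt-Co3 (-0.56) past the test (camera adjusted p = 0.00245, and adjusted p = 0.695 with an estimated correlation).

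In cluster 14 as a whole 86 genes were higher and 127 lower of 9791. DESeq2 called 66 and 73, and with sex as a block the counts were 160 and 213. Gdf15 did not pass with sex as a block (adjusted p = 0.0514), nor Mrc1 with doublets kept (0.0832). The total of 213 became 122 without the Csf2+/- male library, 135 without the Csf2+/- female, 353 without the Csf2-/- female and 375 without the Csf2-/- male library. H2-Eb1, H2-Ab1, H2-Aa and Cd74 did not pass without the Csf2-/- male library (adjusted p = 0.0863, 0.169, 0.214 and 0.240), nor did H2-Ab1 and H2-Aa without the Csf2+/- female library (0.0745 for both). Without the Csf2+/- male library H2-Ab1, H2-Aa, Cd74, Mrc1, Socs3 and mt-Co3 did not pass (0.0700 to 0.0906), and without the Csf2-/- female library Cd74 and mt-Co3 did not (0.0929 and 0.120).

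Type 2 conventional dendritic (cDC2)-like cells had more genes past the test than any other named class, and those induced through STAT5 were prominent. Ccl17, a chemokine gene, fell from 186.6 ± 5.89 to 12.1 ± 2.95 CPM (SD, n = 2 per genotype; log2 -3.92, SE 0.13, edgeR adjusted p = 1.43e-08). Ccl17 is also a leading gene of migratory dendritic-like cells, at 1629 CPM there in Csf2+/- libraries. Of the other leading genes of those cells, Ccr7 fell in cDC2-like cells (-1.26, SE 0.25, adjusted p = 0.0170), while Ccl22 (-1.15, adjusted p = 0.253) and Fscn1 (0.15, 0.911) did not pass. Flrt3 fell from 40.5 ± 3.84 to 0.934 ± 0.577 CPM (log2 -5.35, SE 0.26, adjusted p = 4.68e-07). Of the 25 STAT5-induced genes 10 fell, 1 rose (Arg1, log2 1.70) and 14 did not pass. Those that fell included Cish, a feedback inhibitor of cytokine signalling (-1.84, SE 0.14), the survival genes Bcl2a1a (-1.85, SE 0.15) and Bcl2a1b (-0.95, SE 0.11), and the receptor chain Csf2rb (-0.74, SE 0.09). Adjusted over the list alone, 14 were lower and 1 higher (camera adjusted p = 1.21e-06, and adjusted p = 0.601 with an estimated correlation). Mtss1 (-1.97), Plxdc2 (-1.98) and Il1rl1, the IL-33 receptor gene (-1.08), also fell, as did Lpl (-1.77), which leads cluster 14. Flrt3 and Cish fell in cluster 14 too, whose cells joined cDC2-like ones at the lower Leiden resolution. A shift of cells across that border, or RNA from cluster 14, was not told apart from changes within cDC2-like cells. Gria3 (1.95), Cd7 (1.33), Areg (1.26) and Acp5 (1.24) rose. Areg and Arg1 are leading genes of ILC2-like clusters, and of 16 ILC2 effector genes measured in cDC2-like cells 6 rose: these and Cd69 (0.62), Crlf2 (0.41), Icos (0.91) and Bcl11b (0.98). Il1rl1 is on that list as well, and 9 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000433, and adjusted p = 0.634 with an estimated correlation). Of 29 interferon-response genes, 4 rose, among them Irf7 (0.81) and Ifi47 (0.60), and Cxcl10 fell (-0.61), with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.54e-05, and adjusted p = 0.634 with an estimated correlation). In the same cells 5 of 13 mitochondrial transcripts were lower, for example mt-Nd3 (-0.80) and mt-Co3 (-0.43), with camera adjusted p = 0.0114, and adjusted p = 0.818 with an estimated correlation.

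The cDC2-like counts were 154 higher and 260 lower of 10809 genes, and DESeq2 called 76 and 167. The counts were 374 and 503 with sex as a block. With doublets kept Ccl17 (log2 -3.02, adjusted p = 0.295), Il1rl1 (0.0963), Lpl (0.0926), Cxcl10 (0.144), Ccr7 (0.205), Crlf2 (0.0554) and Bcl11b (0.389) did not pass, and by DESeq2 Arg1, Ifi47, Ccr7, Icos and Bcl11b did not (0.0954 to 0.276). Without the Y-positive cells of the Csf2-/- female library Ccl17 (log2 -4.31, adjusted p = 0.131), Icos (0.0912) and Bcl11b (0.0581) did not pass. The total of 414 became 252 without the Csf2+/- female library, where Arg1, Cxcl10, Ccr7, Cd69, Crlf2 and Bcl11b did not pass (adjusted p from 0.0736 to 0.274), and 203 without the Csf2+/- male library, where Arg1, Ifi47, Cd69, Crlf2 and Icos did not (0.0836 to 0.223). Without the Csf2-/- male library Icos and Bcl11b did not pass (0.0546 and 0.149). Lpl did not pass without the Csf2-/- female or male library (0.0732 and 0.186), nor mt-Nd3 without the Csf2-/- female library (0.0599).

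**Figure D4:**
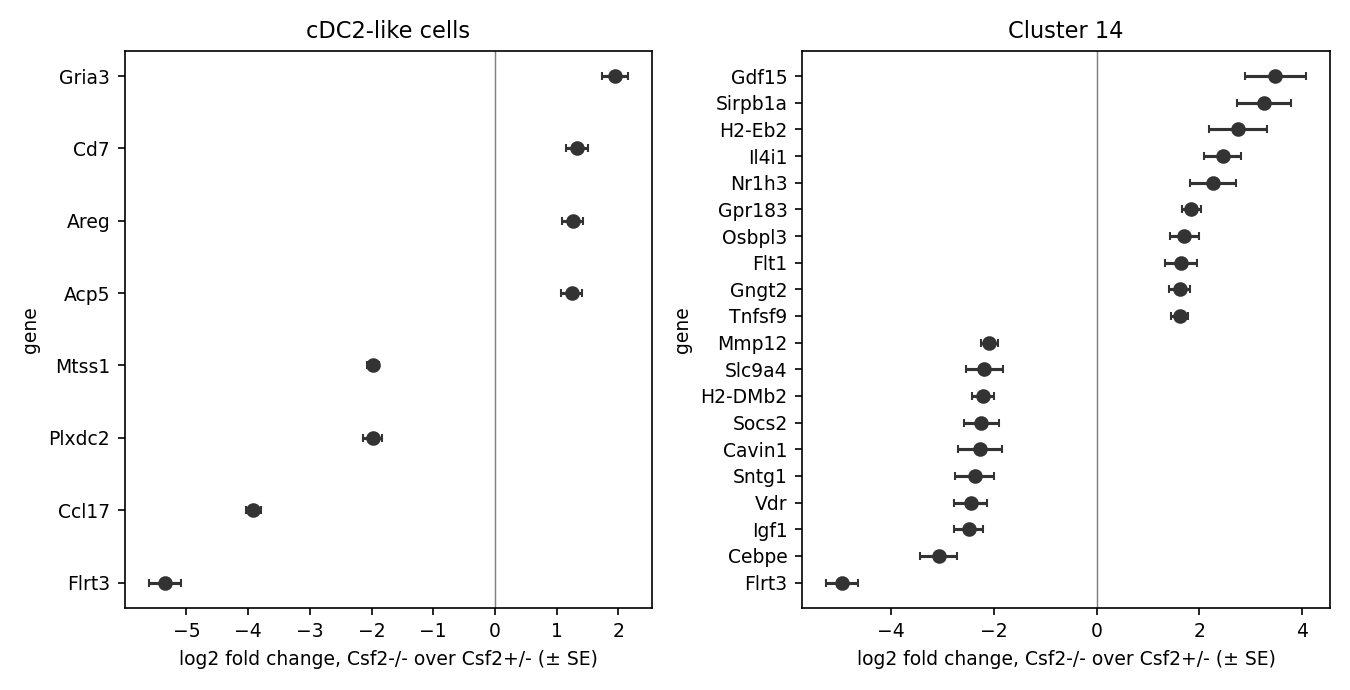
Log2 fold change, Csf2-/- over Csf2+/-, with its standard error as derived from the F statistic, of 8 genes in cDC2-like cells and 20 genes in cluster 14. Values run from -5.35 to 1.95 in cDC2-like cells and from -4.96 to 3.48 in cluster 14.

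In cDC1-like cells, which cross-present antigen, Itgae, the gene of the integrin CD103, fell from 142.1 ± 9.28 to 15.4 ± 3.10 CPM (SD, n = 2 per genotype; log2 -3.23, SE 0.16, edgeR adjusted p = 7.58e-10). Clec7a (-1.92, SE 0.22), Spint1 (-1.98, SE 0.29) and Axl, a receptor for dying cells (-1.75, SE 0.27), fell as well, and Cd69 (1.03, SE 0.20), Ctla2a (1.03, SE 0.24) and Hmmr (1.00, SE 0.22) rose. Of 21 STAT5-induced genes 4 fell, Bcl2a1a (-1.60), Bcl2a1b (-1.47), Bcl2a1d (-0.79) and Csf2rb (-0.63), and 17 did not pass. Adjusted over the list alone, 8 were lower and 1 higher (camera adjusted p = 0.000179, and adjusted p = 0.488 with an estimated correlation). Of 7 ILC2 effector genes Cd69 rose, with 2 higher adjusted over the list alone (camera adjusted p = 0.00223, and adjusted p = 0.488 with an estimated correlation). The mitochondrial transcripts mt-Nd3 (-0.69) and mt-Co3 (-0.45) fell in these cells too. Of 9020 genes 12 were higher and 80 lower, and DESeq2 called 1 and 46. Ctla2a did not pass with doublets kept or with sex as a block (adjusted p = 0.180 and 0.0637), nor Csf2rb with doublets kept or by DESeq2 (0.0511 and 0.109), nor Hmmr with sex as a block (0.0765). DESeq2 gave no adjusted p for Clec7a, Spint1, Axl, Cd69, Ctla2a and Hmmr. The total of 92 became 51 without the Csf2+/- male library, 354 without the Csf2-/- female and 155 without the Csf2-/- male library. Without the Csf2+/- female library Cd69, Ctla2a, Csf2rb and mt-Co3 did not pass (adjusted p from 0.0717 to 0.173), without the Csf2+/- male library Cd69, Ctla2a, Hmmr, Bcl2a1d, mt-Nd3 and mt-Co3 did not (0.0540 to 0.329), and without the Csf2-/- male library Ctla2a and Hmmr did not (0.407 and 0.161).

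In migratory dendritic-like cells the chemokine gene Ccl22 fell from 2602 ± 164 to 1445 ± 123 CPM (SD, n = 2 per genotype; log2 -0.81, SE 0.10, edgeR adjusted p = 0.00223). Adam23 (-1.53, SE 0.13), Fgf13 (-2.42, SE 0.28) and Mtss1 (-1.49, SE 0.26) fell, and Clec4a1 (3.18, SE 0.56) and Gria3 (1.51, SE 0.24) rose. Of 23 STAT5-induced genes Ccl22 and Bcl2a1a (-0.58) fell and 21 did not pass. Adjusted over the list alone, 7 were lower and 1 higher (camera adjusted p = 0.000909, and adjusted p = 0.441 with an estimated correlation). Of 11 ILC2 effector genes 10 had higher values, with 0 past edgeR over all genes (7 at an unadjusted p under 0.05, 0 by DESeq2) and 5 higher adjusted over the list alone (camera adjusted p = 7.76e-05, and adjusted p = 0.441 with an estimated correlation). mt-Nd3 fell by 0.74 on the log2 scale. Of 7968 genes 7 were higher and 14 lower, and DESeq2 called 11 and 16. Both directions had more calls with sex as a block, 46 and 42. With doublets kept Ccl22 (log2 -0.77, adjusted p = 0.117), Mtss1, Clec4a1, Gria3, Bcl2a1a and mt-Nd3 (0.0589 to 0.749) did not pass, by DESeq2 Mtss1 and mt-Nd3 did not (0.317 and 0.0955), nor Mtss1, Bcl2a1a and mt-Nd3 without the Y-positive cells of the Csf2-/- female library (0.0558 to 0.0684). The total of 21 rose to between 108 and 202 when any 1 library was left out: 113 and 108 without the Csf2+/- female and male libraries, 202 and 171 without the Csf2-/- ones. Clec4a1 did not pass without the Csf2-/- male library (adjusted p = 0.254).

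In monocyte-like cells 4 of 12 measured MHC class II genes rose in Csf2-/- libraries. H2-Eb1 rose from 182.9 ± 1.52 to 388.2 ± 66.0 CPM (SD, n = 2 per genotype; log2 1.08, SE 0.11, edgeR adjusted p = 7.69e-05), and H2-Ab1 (0.97, SE 0.10), H2-Aa (0.85, SE 0.10) and Cd74, the class II invariant chain gene (0.51, SE 0.08), rose with it. With doublets kept none of these passed (log2 0.60, 0.52, 0.42 and 0.27, adjusted p = 0.113, 0.112, 0.0547 and 0.122). All of them also lead the cDC2-like clusters, as does Cd209a, at 1039 CPM in Csf2+/- cDC2-like cells. Cd209a rose alongside them in monocyte-like cells, from 12.97 ± 1.44 to 25.1 ± 0.857 CPM (log2 0.95, SE 0.19, adjusted p = 0.0270), but it did not pass with doublets kept (0.126), by DESeq2 (0.340) or whichever library was left out (0.0757 to 0.454). Of the class II list 7 were higher adjusted over the list alone (camera adjusted p = 7.11e-05, and adjusted p = 0.932 with an estimated correlation). Of 22 proliferation genes Stmn1 (1.20) and Pclaf (1.65) rose and 20 did not pass, with the same 2 counted adjusted over the list alone (camera adjusted p = 2.20e-07, and adjusted p = 0.556 with an estimated correlation). The cyclin gene Ccnd1 (1.53) and Clec4b1 (1.24) rose, as did the immediate early genes Fos and Jun (0.56 each), which tissue digestion can raise, and Pde3b (-0.81) and Lpp (-0.71) fell. mt-Nd3 (-0.59) and mt-Co3 (-0.36) fell in these cells. Of 9647 genes 20 were higher and 33 lower, and DESeq2 called 12 and 19, where Stmn1 did not pass (adjusted p = 0.0976) and Pclaf had no adjusted p. Fitted with sex as a block, 163 and 199 passed, and with doublets kept mt-Co3 did not pass (0.0521). The total of 53 became 142 without the Csf2+/- female library, 26 without the Csf2-/- female and 11 without the Csf2-/- male library. Among the genes named here other than Cd209a, H2-Eb1 and H2-Ab1 passed without any 1 library. Without the Csf2-/- male library the others except Stmn1 did not pass (adjusted p from 0.0567 to 0.593), and without the Csf2-/- female library Cd74, Stmn1, Pclaf, Fos, Jun, mt-Nd3 and mt-Co3 did not (0.0612 to 0.269). Stmn1 and Pclaf did not pass without the Csf2+/- female library (0.0630 and 0.0737), nor did these, mt-Nd3 and mt-Co3 without the Csf2+/- male library (0.0529 to 0.204).

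In lymphoid, eosinophil-like and epithelial-like cells, with genotype as the only term, between 0 and 24 genes passed per class. In ILC2-like cells the 2 lower genes were Csf2 and Retnla (log2 -3.78, and -1.70 with adjusted p = 0.762 with doublets kept). Retnla was also the 1 gene lower in NK and ILC1-like cells (-3.12), and it fell in gamma-delta T-like (-2.38) and migratory dendritic-like cells (-4.18). It is the leading gene of cluster 14, at 10231 CPM in that cluster in Csf2+/- libraries. In B-like cells Fn1 (-3.76) and Ccl9 (-2.73), which also lead cluster 14, fell. Igkc rose in B-like cells (0.30), but with doublets kept it was -0.32. In T-like cells the macrophage genes C1qa (1.13), Pf4 (1.22) and Csf1r (1.19) rose, and Il23r (-2.03), Trdc, a gamma-delta T cell gene (-0.58), and mt-Nd3 (-0.71) fell. In gamma-delta T-like cells Hspa5 (0.61) and Ccl5 (1.90) rose, the latter turning to -0.59 with doublets kept, and Bambi (-1.20) and Grap2 (-0.72) fell. In eosinophil-like cells Apoe rose (1.19) and the salivary secretory genes Pip (-1.07) and Prol1 (-1.23) fell. In B-like cells Ccl9 and Igkc did not pass without the Csf2+/- male library (adjusted p = 0.894 and 0.749), nor Ccl9 without the Csf2-/- female library (0.509). In T-like cells Csf1r, Pf4, Il23r and Trdc did not pass without the Csf2+/- female library (0.0739 to 0.247), Csf1r and Pf4 without the Csf2+/- male library (0.0821 and 0.0569), nor Csf1r, Il23r, Trdc and mt-Nd3 without the Csf2-/- female library (0.0558 to 0.204). The gamma-delta T-like genes named did not pass without the Csf2+/- female or male library (0.114 to 0.497), nor Hspa5 without the Csf2-/- male library (0.135). With doublets kept Ccl9, Il23r, Pip and Prol1 did not pass (0.710, 0.174, 0.0754 and 0.0754). By DESeq2 Fn1, Apoe, Pip and Prol1 did not (0.0553, 0.0912, 0.123 and 0.0982), nor Ccl9 and Igkc, and Ccl9 did not with sex as a block (0.106). DESeq2 gave no adjusted p for Retnla in ILC2-like, Csf1r and Il23r in T-like and Retnla, Ccl5 and Bambi in gamma-delta T-like cells.

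The higher and lower counts by edgeR were 0 and 2 of 11582 genes in ILC2-like, 0 and 1 of 12958 in NK and ILC1-like, 2 and 22 of 7266 in B-like, 5 and 5 of 10739 in T-like, 2 and 3 of 9488 in gamma-delta T-like and 1 and 2 of 2073 in eosinophil-like cells. In epithelial-like cells edgeR called 0 of 10064, with 888 at an unadjusted p under 0.05, and DESeq2 called 10 higher and 8 lower. DESeq2 called 4 and 65 genes in ILC2-like and 21 and 29 in NK and ILC1-like cells. With sex as a block the counts were 0 and 9 in ILC2-like, 51 and 100 in NK and ILC1-like, 2 and 11 in B-like, 98 and 120 in T-like, 29 and 59 in gamma-delta T-like and 5 and 9 in eosinophil-like cells, and 0 in epithelial-like cells with 586 at an unadjusted p under 0.05. Leaving out single libraries moved these counts by over 1.5 times. For the Csf2+/- female, Csf2+/- male, Csf2-/- female and Csf2-/- male library in turn they became 4, 4, 9 and 8 in ILC2-like, 3, 1, 52 and 20 in NK and ILC1-like, 34, 7, 200 and 111 in epithelial-like and 0, 0, 63 and 28 in gamma-delta T-like cells. In the same order they were 59, 21, 28 and 41 in B-like, 7, 22, 10 and 24 in T-like and 6, 14, 18 and 23 in eosinophil-like cells.

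Between the sexes, macrophage-like cells differed in 294 genes. Cxcl9, an interferon-induced chemokine gene, was higher in male libraries (25.4 ± 1.58 against 8.91 ± 1.73 CPM, SD, n = 2 per sex; log2 1.499, SE 0.14, edgeR adjusted p = 0.00114), as was Ccl8 (1.02, SE 0.08). Auts2 (0.84) and Cdca2 (0.83) were also higher, and Retnla (-0.97, SE 0.07), Ly6c2 (-1.05, SE 0.14) and Cd3d, a T cell gene (-1.19, SE 0.15), were lower in males. Gm26992 was at 76.8 CPM in female and 0.246 CPM in male libraries (log2 -8.27). Of the Y-linked genes Kdm5d, at 0.0869 ± 0.123 CPM in female and 13.3 ± 1.04 CPM in male libraries, passed (adjusted p = 4.32e-05), while Ddx3y, Eif2s3y and Uty, at 0.840, 0.405 and 0.347 CPM in females and 101.9, 58.5 and 61.7 CPM in males, did not (adjusted p = 0.286, 0.118 and 0.0627). The Csf2-/- female library held all the Y-linked UMIs of the female macrophage-like cells. With genotype in the model, edgeR called 140 genes higher and 154 lower in males of 12669, and DESeq2 21 and 39.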

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

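The re-clustering test and the test of GM-CSF targets in cluster 14, and the tests for residual Csf2, were chosen after the result was seen. So were the calculation over all 22 measured ILC2 effector genes and its sign test, added once a version over 16 genes had been computed.

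A signal of Y-linked genes appeared in a female library. In the Csf2-/- female library 1.72% of barcodes (168 of 9752) held a Y-linked UMI and 88 held at least 3, against 0.0627% (6 of 9567) in the Csf2+/- female library. The shares were 85.9% and 83.4% in the male libraries. Without those cells edgeR called 221 genes higher and 235 lower in male macrophage-like cells.

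Cluster 14 held a smaller share in both Csf2-/- libraries. Clustering without its leading and genotype-called genes left a log2 change of -1.81 (SE 0.37) in the group made up mostly of its cells. Altered Csf2-/- cells in a group of their own would not be counted there, so this does not decide whether cells were reassigned. Among cells with 5000 to 20000 UMIs the change was -2.20, with shares of 2.44% and 3.41% against 0.632% and 0.640% and no overlap of exact intervals. The change thus remained within that range. Its median UMIs were still 10546 and 10163.5 in Csf2+/- against 9141 and 9003.5 in Csf2-/- libraries, so depth was not held equal and its part is not decided. Loss of GM-CSF signalling in these cells stays open: STAT5-induced genes in the remaining cells gave adjusted p = 0.0702 by camera, which compares the list with other genes (adjusted p = 0.679 with an estimated correlation), and 0.0462 by fry, which tests only whether the list moved one way. It is a candidate explanation, and a lack of survival, of entry or of maturation could each give the same share.

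ILC2 effector genes had higher values in Csf2-/- macrophage-like cells. Droplets shared with lymphocytes could account for most of this: without the lymphocyte-led subsets the median log2 change of the 22 measured genes went from 0.35 to 0.13, leaving 36.3%, and the number higher from 17 to 13. An exact two-sided sign test with the subsets gave p = 0.0169, but it treats the genes as independent. The list had adjusted p = 0.686 by camera with an estimated correlation and 0.481 by fry. Over the 16 genes that passed the low-count filter, the median went from 0.15 to -0.08 and 11 higher became 7 (-51.1% left, exact sign test p = 0.210 with the subsets), and leaving out subsets chosen by lymphocyte genes can also remove cells that truly express them. Free RNA of ILC2s cannot be told apart. The 5% of macrophage-like cells with the most such UMIs held 2.49 to 3.50 times the share that scattering by depth gives. The bounds set beforehand were at most 1.5, or at least 3 in every library, and only the Csf2-/- male library lay above 3.

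Some Csf2 UMIs remained in ILC2-like cells of Csf2-/- libraries. Positive cells there held 1.18 Csf2 UMIs each against 5.04 in Csf2+/- libraries, a ratio of 0.234, which argues against whole Csf2+/- cells mixed in. The share in ILC2-like cells was 32.9 times that in other cells, which argues against free RNA and against reads passed between libraries, since the latter keep their barcode and barcodes fall on cells of every class alike. Transcription from the altered allele may account for them, and it was not tested.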

How the results depend on the processing

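There were 2 libraries per genotype, and counts of called genes moved with the model and with single libraries. The eosinophil-like call was lost with the higher UMI minimum, and the Csf2 shares fell with thinning. The settings named at the end of the processing summary as added, and the thinning of Csf2 shares, were chosen after seeing the data. Over all settings, 167 single class shares kept their direction and side of the threshold, 6 became weaker, 4 stronger and 11 reversed. For gene lists these numbers were 142, 46, 8 and 11, and for named genes 3274, 408, 99 and 40. Of the counts of calls 66 stayed within 1.5 times and 116 did not. The 2 genotypes share no replicate number to pair by, but each has 1 female and 1 male library, and the fit with sex as a block pairs these. At Leiden resolution 0.8 cluster 14 has no value of its own, since its cells joined cDC2-like ones. Sex could not be fitted with a library left out, since no residual degrees of freedom remain. Where 1 library is left out, the lone library is assumed to vary like the other genotype. For the values that follow, the cause was not tested.

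Numbers of called genes moved most. With DESeq2 they were 30 in macrophage-like, 1 in B-like, 139 in cluster 14, 0 in eosinophil-like (39 at an unadjusted p under 0.05, and 3 by edgeR), 18 in epithelial-like, 69 in ILC2-like, 31 in monocyte-like, 50 in NK and ILC1-like, 47 in cDC1-like, 243 in cDC2-like and 12 in gamma-delta T-like cells, 27 in macrophage cluster 6 and 60 between sexes. With no low-count filter they were 34 in macrophage-like, 42 in B-like, 657 in cluster 14, 16 in eosinophil-like, 105 in epithelial-like, 298 in ILC2-like, 218 in migratory dendritic-like, 205 in monocyte-like, 112 in NK and ILC1-like, 171 in T-like, 291 in cDC1-like, 870 in cDC2-like and 61 in gamma-delta T-like cells, 254 and 461 in macrophage clusters 4 and 6 and 1024 between sexes. With sex as a block they were 437 in macrophage-like, 13 in B-like, 373 in cluster 14, 14 in eosinophil-like, 9 in ILC2-like, 88 in migratory dendritic-like, 362 in monocyte-like, 151 in NK and ILC1-like, 218 in T-like, 877 in cDC2-like and 88 in gamma-delta T-like cells, and 193 and 246 in macrophage clusters 4 and 6. With doublets kept they were 1 in B-like, 1 in eosinophil-like, 12 in ILC2-like, 3 in NK and ILC1-like, 32 in T-like and 9 in gamma-delta T-like cells. In macrophage-like cells the count was 90 without lymphocyte-led subsets and with sex as a block. It was 615 with cluster 14 added, where the smaller Csf2-/- share of that cluster lowers its genes in the sums. Between sexes it was 456 without the Y-positive cells of the Csf2-/- female library.

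Shares and lists moved less. With sex as a block 0 classes passed, and the eosinophil-like change was -1.39 and that of cluster 14 -2.33, neither past the threshold. With TMM factors 2 classes passed, the gamma-delta T-like change was 1.19 and past the threshold, and the monocyte-like, neutrophil-like and cDC2-like changes turned to 0.14, 0.087 and 0.061. With the stricter cell filter 0 classes passed and the eosinophil-like change was -0.83, and with its UMI minimum alone 0 passed and the change was -0.73. Among the named mononuclear phagocyte classes, without cluster 14, the migratory dendritic-like change was -0.88 and past the threshold. With an estimated correlation 0 macrophage lists passed, and by fry 0. Thinned to 3000 UMIs, the ILC2-like shares with a Csf2 UMI were 13.4%, 15.7%, 1.67% and 1.11%.

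Some log2 values of named genes changed sign. With doublets kept they were -0.32 for Igkc in B-like cells, -0.062 for Fscn1 and 0.18 for Lyz1 in macrophage-like cells and -0.59 for Ccl5 in gamma-delta T-like cells. Without lymphocyte-led subsets Icos was at -1.28 and Itgb7 at -0.048 in macrophage-like cells. With limma-voom Ddx3y, Eif2s3y, Kdm5d and Uty were at 2.72, 2.17, 1.20 and 2.08 there, and Ddx3y was at 0.0078 with sex as a block. In cluster 14 Csf1r was at -0.015 with no low-count filter and Itgax at -0.058 with the stricter cell filter. Without the Y-positive cells Pparg in cDC2-like cells was at -0.0085, and the sex-linked list turned with adjusted p = 0.994.

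Leaving out each library in turn gave 0 to 399 called genes in macrophage-like, 21 to 59 in B-like, 122 to 375 in cluster 14, 6 to 23 in eosinophil-like, 7 to 200 in epithelial-like, 4 to 9 in ILC2-like, 108 to 202 in migratory dendritic-like, 11 to 142 in monocyte-like, 1 to 52 in NK and ILC1-like, 7 to 24 in T-like, 51 to 354 in cDC1-like, 203 to 539 in cDC2-like and 0 to 63 in gamma-delta T-like cells, and 3 to 272 and 0 to 508 in macrophage clusters 4 and 6. It gave 0 to 3 classes past the threshold, 0 to 2 macrophage subsets and 3 to 14 macrophage lists. Share changes ran from -1.58 to -1.22 (eosinophil-like), 0.13 to 1.04 (epithelial-like), -0.059 to 0.66 (ILC2-like), -0.93 to -0.60 (migratory dendritic-like), -0.24 to 0.25 (monocyte-like), -0.67 to 0.42 (neutrophil-like), -0.63 to 0.13 (T-like), -0.038 to 0.27 (cDC1-like) and -0.28 to 0.093 (cDC2-like). Lists that turned had adjusted p from 0.357 to 0.942 (glycolysis), 0.259 to 0.896 (efferocytosis), 0.0127 to 0.830 (monocyte-derived), 0.00223 to 0.969 (dissociation stress), 1.11e-08 to 0.347 (salivary epithelium) and 0.0202 to 0.786 (sex-linked). Genes that turned ran from -0.26 to 0.53 (Cd163), -0.060 to 0.11 (Csf1r), -0.57 to 0.46 (Csf2rb2) and -0.18 to 0.27 (Itgax) in cluster 14. In macrophage-like cells they ran from -0.022 to 0.61 (Cd163), -0.29 to 0.11 (Csf2ra), -4.98 to 12.70 (Ddx3y), -5.28 to 11.84 (Eif2s3y), -0.051 to 0.30 (Folr2), -0.95 to 8.80 (Hbb-bs), -0.39 to 0.025 (Itgax), -5.29 to 9.75 (Kdm5d), -0.11 to 0.56 (Mrc1) and -5.57 to 11.92 (Uty). In cDC2-like cells they ran from -0.058 to 0.21 (Csf2ra), -0.075 to 0.48 (Folr2) and -0.18 to 0.21 (Pparg).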

Other observations

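The tests of lists in classes other than macrophage-like cells, and of macrophage-like cells with cluster 14 added, were chosen after the result was seen.

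Interferon-stimulated genes, which mark a response to interferon, lay in opposite directions in different Csf2-/- classes. In ILC2-like cells 24 of 27 had higher values (median log2 0.32), with 0 past the edgeR test over all genes (12 at an unadjusted p under 0.05, 0 by DESeq2) and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.47e-08, and adjusted p = 0.627 with an estimated correlation). In NK and ILC1-like cells 27 of 30 had higher values (median 0.21), with 0 past edgeR over all genes (9 at an unadjusted p under 0.05, 0 by DESeq2) and 0 adjusted over the list alone (camera adjusted p = 3.35e-06, and adjusted p = 0.663 with an estimated correlation). In migratory dendritic-like cells 24 of 25 had lower values (median -0.74), with 0 past edgeR over all genes (10 at an unadjusted p under 0.05, 1 lower by DESeq2) and 7 lower adjusted over the list alone (camera adjusted p = 5.01e-10, and adjusted p = 0.441 with an estimated correlation). The difference between classes was not tested. Of 30 proliferation genes 28 had higher values in ILC2-like cells (median 0.56), with 0 past edgeR over all genes (10 at an unadjusted p under 0.05, 1 higher by DESeq2) and 6 higher adjusted over the list alone (camera adjusted p = 5.32e-08, and adjusted p = 0.627 with an estimated correlation). The numbers were also 28 of 30 in cDC1-like cells (median 0.28), with 6 higher adjusted over the list alone (camera adjusted p = 5.90e-05, and adjusted p = 0.488 with an estimated correlation). There Cenpf alone passed over all genes (log2 0.82, SE 0.16, but adjusted p = 0.164 without the Csf2+/- male library and 0.0801 by DESeq2). ILC2 effector genes had higher values in 17 of 22 cases in NK and ILC1-like cells (median 0.37), with 0 past edgeR over all genes (10 at an unadjusted p under 0.05, 2 higher and 1 lower by DESeq2) and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.35e-06, and adjusted p = 0.356 with an estimated correlation). The mitochondrial list had a median of -0.20 in ILC2-like, -0.17 in NK and ILC1-like, -0.27 in cDC1-like and -0.18 in migratory dendritic-like cells.

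Macrophage-like cells fell into 27 subsets when clustered alone, led for example by Lyve1, Folr2 and Timd4, by Il12b and Il1b, by Top2a and Mki67, or by Rsad2 and Ifit3. Of the 19 subsets with enough cells 0 passed in edgeR as a share, with 1 at an unadjusted p under 0.05, and the smallest adjusted p was 0.483, for a subset led by Ccl5 and Nkg7, which are lymphocyte genes. Another subset lay mostly in the Csf2-/- male library, with 12 and 24 cells in the Csf2+/- female and male and 16 and 125 in the Csf2-/- female and male libraries. Its log2 change was 2.50 without the Csf2-/- female library and -0.51 without the Csf2-/- male library. Adding cluster 14 to the macrophage-like class gave 81 genes higher and 534 lower of 12970. Cluster 14 was rarer in Csf2-/- libraries and differs from macrophage-like cells, for example in Retnla (10231 against 238 CPM in Csf2+/- libraries). Its smaller share alone lowers its genes in the joint sums, so these calls do not show changes within macrophage-like cells. The total of 615 became 121 without the Csf2+/- female library, 99 without the Csf2+/- male, 1373 without the Csf2-/- female and 2051 with sex as a block. A cluster of 74 epithelial-like cells was found in the Csf2-/- female library only.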
